A study of Mus musculus with 6 samples.

How the data were processed

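The series holds 6 libraries of messenger RNA from interscapular brown adipose tissue of male C57BL/6N mice aged 20 weeks, 3 from control mice and 3 from mice held in the cold. Per the labels, poly(A) RNA was selected in 2 rounds and turned into cDNA with the TeloPrime kit, which selects capped, full-length molecules. The cDNA was amplified over 27 PCR cycles, and 400 ng of it was barcoded and ligated for nanopore sequencing. The protocol names no molecular identifiers, so that reads of 1 original molecule cannot be told from reads of several. Each library was run on 2 flow cells, which gave 12 files. The extraction text of every sample names eWAT, a white fat depot, while the tissue and source labels give interscapular brown fat, and the tissue label was used.

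The deposited files give raw counts, the number of reads assigned to each Ensembl transcript on 1 flow cell, with no normalization by the authors. Transcripts without a read are not listed and were taken as 0. The authors name minimap2 and the mouse genome build GRCm38, without a version for minimap2. The way in which a read that fits several transcripts was assigned is not given in the sources used here. Every value was a whole number, and no column of the files was left unused.

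Transcripts were joined to genes through the GENCODE M21 annotation of GRCm38. Of the 14693 transcript identifiers in the files, 14653 matched with their version and 14671 matched without it. The 22 without a match held at most 0.00433% of a library's reads and were left out. Counts were summed over both flow cells of a library, and for genes over all their transcripts. Reads fell on 8129 genes. The 6 libraries, and not the 12 files, were the replicates. Mouse numbers are not shared between the groups, so nothing pairs a control with a cold mouse, and no covariate was fitted.

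Library totals ran from 1014847 to 2982713 reads, a ratio of 2.94, and 13457246 reads were counted in all. A floor of 3 reads corresponds to between 1.01 and 2.96 CPM before TMM scaling, depending on the library, where CPM is the edgeR scale of counts relative to the library total. Floors cover counting error only, since PCR copies are not independent molecules.

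Genes and transcripts were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr by group at its minimum count of 10, libraries were scaled by trimmed mean of M-values (TMM), and cold was compared with control by the robust quasi-likelihood F test. The p values were adjusted by the Benjamini-Hochberg method, and a gene or transcript was called at an adjusted p under 0.05. Log2 changes are cold minus control throughout. Their error is a standard error (SE) worked back from the test, the size of the log2 change divided by the square root of F. Intervals of a log2 change are at the 95% level and rest on this SE, which includes the variation between libraries. Changes in the share of a gene's reads held by each of its transcripts were tested with diffSpliceDGE of edgeR in genes with at least 2 tested transcripts, with Simes p values per gene and Benjamini-Hochberg adjustment.

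Before the data were examined, 31 lists of pathway, complex and cell type genes were written down, along with the alternatives described in the closing section and the rule for naming genes. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. For each list the called members are counted after adjustment over all genes and, separately, adjusted over the list alone. The rule named the 10 largest rises and the 10 largest falls among called genes of at least 32 CPM whose libraries separate completely by group, with pseudogenes and unnamed models skipped. It also named the 3 members with the smallest p in each called list, and a fixed set of brown fat genes wherever they were tested. For transcript usage it named the 8 genes with the smallest adjusted p, plus Ppargc1a and Aifm2, and for transcripts the 3 largest rises and 3 largest falls of at least 32 CPM in genes not called themselves. The rule took 44 genes. A further 102 genes serve as examples of the lists and were chosen after their values were seen, as were list members named because their call changed when 1 library was left out.

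Detected transcripts were counted after each library was thinned to the smallest total. These counts, and the mean annotated length of counted transcripts, were compared by exact two-sided permutation tests over the 10 splits of 6 libraries into 3 and 3, for which the smallest p is 0.1. The flow cells of each library were compared transcript by transcript with an exact binomial test, and all 15 pairs of libraries were compared in the same way. Near-identical copies of a named gene were sought with blastn 2.17.0 at an identity of 98% over 80% of the shorter transcript, among genes holding at least 5% as many reads. Other genes sharing at least 100 exon bases on either strand were sought too.

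The procedures were tested on simulated data of the same size. Among 100 genes changed 2-fold, 31 were recovered, and among 100 changed 4-fold, 87 were recovered, with 9 false calls in 2077 genes. For transcripts these numbers were 28 and 81 of 100, with 14 false calls in 2799. Of 40 genes with switched transcripts, 19 were recovered, with 4 false calls in 545. A shifted list of 16 genes was found by each of the 3 set tests, with 0 false calls. Each gene was drawn independently, so these runs cannot show false calls of set tests that arise from correlated list members. In the real data the estimated correlation within a tested list ran from -0.08 for secreted factors to 0.96 for skeletal muscle. Alternatives covered scaling by DESeq2 1.42.0 size factors or by totals alone, the DESeq2 test, limma-voom, other count filters, each flow cell alone, equal depth, protein-coding transcripts alone and leaving out each library in turn. Removal of each library's trend of counts on annotated length, and leaving out cold replicates 11 and 15 together, were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for preparation and figures.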

Results

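Gene and transcript expression was measured by nanopore sequencing of full-length cDNA in interscapular brown fat, the heat-producing fat depot between the shoulder blades, of 20-week-old male mice. The comparison is of 3 mice held alone at 4 °C for 24 h with 3 control mice. The cold treatment is described on the records of all 6 samples, controls included, so the groups were taken from the sample titles and the treatment tag. For the control mice only the general husbandry temperature of 22 to 24 °C is known. Whether they were also held alone is not known, so an effect of single housing cannot be told apart from that of the cold. Samples are named by group and mouse number. Control replicates 2, 9 and 14 gave 1849431, 1014847 and 1735360 reads, and cold replicates 4, 11 and 15 gave 2923005, 2982713 and 2951890. Every cold library was thus deeper than every control library, so depth and group cannot be told apart in the counts as deposited. Reads were seen on 4079 to 4665 genes per control library and on 5279 to 5478 per cold library. All levels below are normalised read counts on the CPM scale of edgeR, given as mean ± SD over n = 3 libraries per group, changes are log2 cold minus control ± SE, and adjusted p values are Benjamini-Hochberg values from edgeR unless a set test is named.

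The title of the series gives the complexity of the brown fat transcriptome as its subject. The deposited counts allow only the number of annotated transcripts seen to be compared, and they say nothing of transcripts outside the annotation. At equal depth the control libraries held 6176 ± 137 transcripts (SD, n = 3) and the cold libraries 6286 ± 139. The difference of 110 lay within the spread between replicates (exact two-sided permutation p = 0.5, smallest possible 0.1). With at least 3 reads per transcript the difference was 64.3 (exact permutation p = 0.4), and for genes, at 3977 ± 89.0 against 4056 ± 61.0, the exact permutation p was 0.3. The mean annotated length of counted transcripts was 1453 ± 77.5 nucleotides in control and 1556 ± 24.4 in cold libraries. Each cold library lay above each control library, which gave the smallest p the design allows (difference 102, exact permutation p = 0.1). The median length overlapped between the groups, at 1111 ± 111 against 1259 ± 74.1 (exact permutation p = 0.2). Without control replicate 2 the difference of the means was 57.9.

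The flow cells of a library gave the same counts within sampling noise. In each library 2 or 3 of 1894 to 3128 transcripts differed between flow cells at adjusted p under 0.05 by exact binomial test, at most 0.106% of them. Between libraries of a group 11.9 to 26.8% of transcripts differed, and between groups 33.6 to 44.8%, so that no pair of samples was 1 library deposited under different names. Across genes, which are not independent replicates, log CPM correlated at 0.962 to 0.983 within groups and at 0.891 to 0.932 between them. The first principal component, with 65.9% of the variance, separated the groups.

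Cold exposure was compared with control to ask which genes of brown fat differ after 24 h alone at 4 °C. Gmpr, which encodes the guanosine monophosphate reductase of purine recycling, rose from 168 ± 13.1 to 4133 ± 692 CPM (4.62 ± 0.19, adjusted p = 1.4e-07). Ckb, the brain-type creatine kinase, rose from 13.5 ± 2.37 to 394 ± 204 CPM (4.86 ± 0.41, adjusted p = 2.1e-05), and Adcy3, an adenylyl cyclase that makes cyclic AMP, rose from 5.03 ± 2.82 to 135 ± 26.2 CPM (4.76 ± 0.38, adjusted p = 1.7e-05). The control level of Adcy3 rested on few reads, at 2.16, 5.14 and 7.80 CPM in control replicates 2, 9 and 14. The 3-read floors of these libraries were 1.62, 2.96 and 1.73 CPM. Fasn, the fatty acid synthase, fell from 757 ± 316 to 46.4 ± 20.4 CPM (-4.03 ± 0.42, adjusted p = 9.1e-05). Lpl, the lipoprotein lipase that frees fatty acids from circulating triglycerides, rose 3.86-fold from an already high level, 4637 ± 1248 to 17887 ± 1486 CPM (1.95 ± 0.19, adjusted p = 4.4e-05). Ucp1, the uncoupling protein of heat production, stood at 4520 ± 335 CPM in control and 4129 ± 45.0 CPM in cold (-0.13 ± 0.13, adjusted p = 0.475).

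The other large rises were of Nnmt, the nicotinamide methyltransferase (3.90 ± 2.51 to 106 ± 7.39 CPM, 4.84 ± 0.39), and Cars2, the mitochondrial cysteinyl-tRNA synthetase (13.3 ± 2.77 to 338 ± 124 CPM, 4.69 ± 0.33). They also included the tetraspanin Tspan18 (4.63 ± 0.58), the cytosolic aspartate aminotransferase Got1 (11.0 ± 1.16 to 206 ± 48.6 CPM, 4.23 ± 0.27), the ciliary neurotrophic factor receptor Cntfr (4.09 ± 0.31), Adtrp (3.77 ± 0.27) and the cytochrome P450 gene Cyp4b1 (3.77 ± 0.27). Among called genes with an average of at least 32 CPM, the largest falls included Tmem45b (934 ± 152 to 50.1 ± 15.7 CPM, -4.22 ± 0.28) and the carbonic anhydrase Car3 (606 ± 65.1 to 36.7 ± 5.04 CPM, -4.04 ± 0.22). Slc25a1, the mitochondrial citrate carrier, fell by 3.86 ± 0.33 and the fatty acid desaturase Scd1 fell from 1767 ± 867 to 152 ± 73.3 CPM (-3.54 ± 0.51). Further falls were of the lipid hydrolase gene Pnpla3 (-3.41 ± 0.39), the aldehyde dehydrogenase Aldh1a7 (-3.14 ± 0.33), Mmd (-3.11 ± 0.43), the malic enzyme Me1 (-3.07 ± 0.58) and the transketolase Tkt (-2.69 ± 0.23). Adjusted p values of these 16 genes lay between 1.3e-06 and 0.00599. That all 3 cold libraries lie on 1 side of all 3 controls was a condition of the rule that named them, and so adds no evidence. Exons of Mmd overlap those of Gm45716, whose reads cannot always be told from those of Mmd. Nnmt stood at 1.20 CPM in control replicate 14, under the 3-read floor of 1.73 CPM of that library.

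On GRCm38, Gmpr (ENSMUSG00000000253) lies on chromosome 13 from 45507444 to 45553800 and Ckb (ENSMUSG00000001270) on chromosome 12 from 111669361 to 111672338. Adcy3 (ENSMUSG00000020654) lies on chromosome 12 from 4133103 to 4213525 and Fasn (ENSMUSG00000025153) on chromosome 11 from 120805846 to 120824547. Lpl (ENSMUSG00000015568) lies on chromosome 8 from 68880491 to 68907448 and Ucp1 (ENSMUSG00000031710) on the same chromosome from 83290352 to 83298452.

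**Figure D1:**
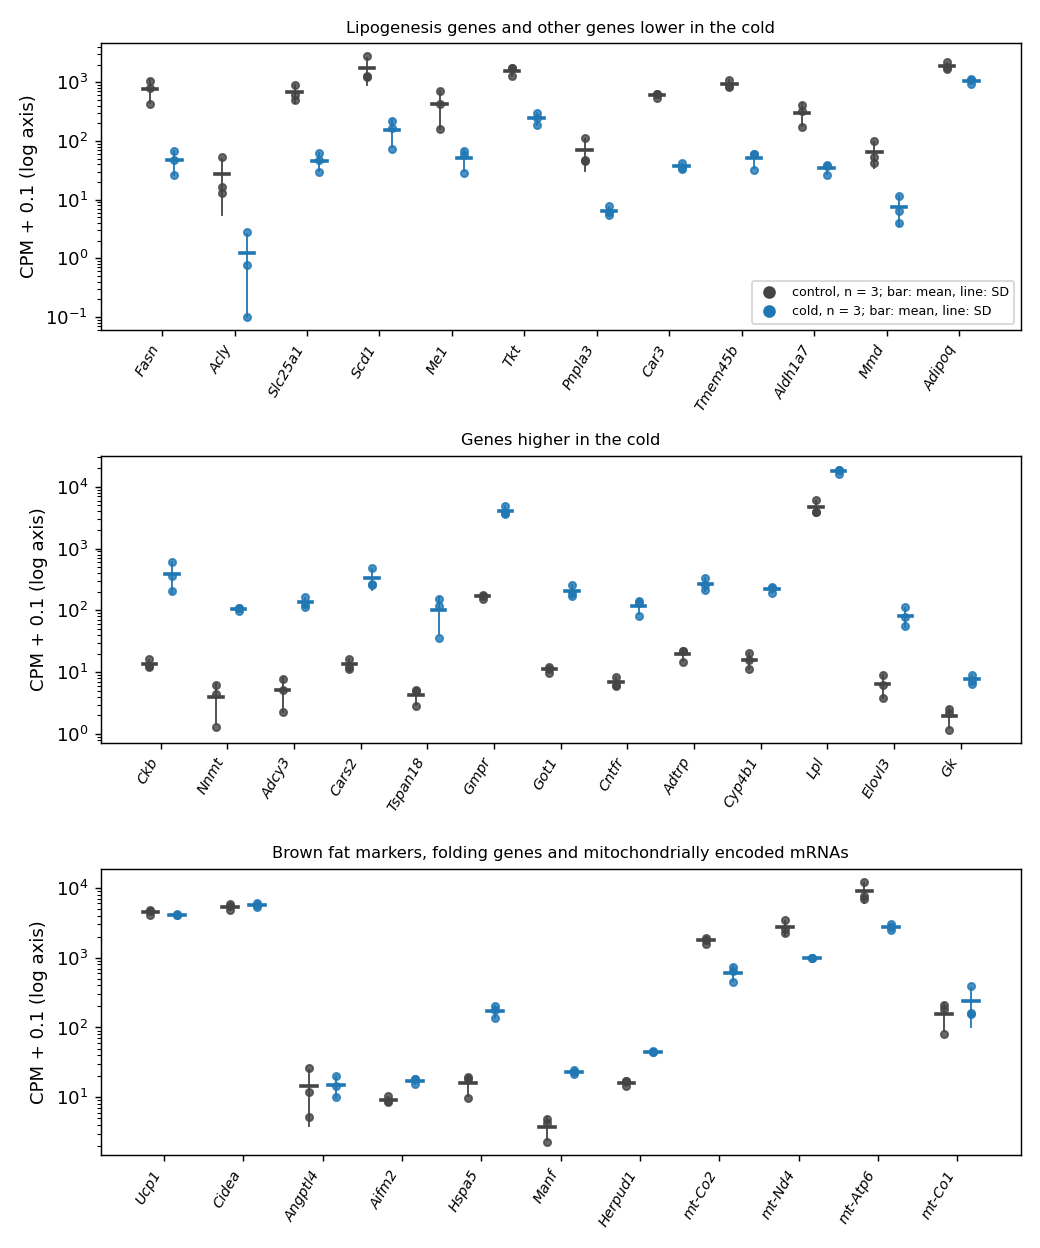
The level of named genes is shown per library as CPM plus 0.1 on a log axis, with the mean and SD of each group of n = 3. Lpl, Gmpr, Ckb and Adcy3 are higher in each cold library than in each control library, Fasn is lower in each, and the values of Ucp1 overlap between the groups.

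Of 2093 genes tested by edgeR, 695 were called, 378 higher and 317 lower in cold, or 33.2%, and 920 had an unadjusted p under 0.05. The tested genes held at least 99.5% of each library's reads. Of the called genes, 270 were at least 2-fold higher and 220 at least 2-fold lower. All 3 cold libraries lay on 1 side of all 3 controls in 1000 of all 2093 genes, which are not independent, where chance gives 10%. They did so in 680 of the 695 called genes, but the calls rest on the same values, so chance gives no comparison there. A near-identical copy holds reads for 38 of the called genes, and 36 share exon sequence with another gene. At equal depth 532 genes were called, and 512 of the 589 earlier calls still tested were called in the same direction. With cold replicates 11 and 15 left out together, an alternative chosen after seeing the data, 321 genes were called, 311 of them among the 695. With protein-coding transcripts alone, 1700037H04Rik was the only called gene to be called in the opposite direction.

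**Figure D2:**
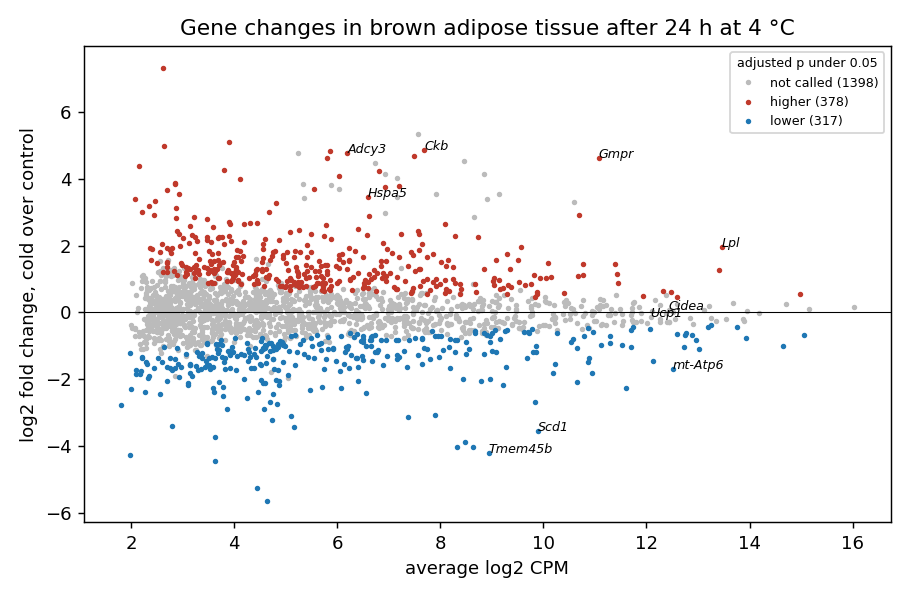
The log2 change of each of the 2093 tested genes, cold minus control, is plotted against its average level in log2 CPM, with called genes coloured by direction. The 378 genes called higher and 317 called lower include Gmpr at 4.62, Lpl at 1.95 and Scd1 at -3.54, while Ucp1 lies at -0.13 among the genes that were not called.

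The fixed gene lists group these changes. Over all 2093 tested genes 33.2% were called, so a list with about that share of called members does not stand out by its count. Of the 31 lists 19 had 5 or more tested members, and camera called 6 of them, 4 lower and 2 higher, while with an estimated correlation it called 0. The lower lists were de novo lipogenesis, mitochondrially encoded mRNAs, the nuclear respiratory chain and cytosolic ribosomal proteins, and the higher ones were endoplasmic reticulum folding and heat shock proteins. With an estimated correlation 1 list, endoplasmic reticulum folding, had an unadjusted p under 0.05 (p = 0.0222), while fry called 8. The 8 were de novo lipogenesis, lipid uptake, mitochondrially encoded mRNAs and proteasome genes (adjusted p = 0.0237 each), endoplasmic reticulum folding (adjusted p = 0.00109), thermogenesis (adjusted p = 0.0345), and secreted factors and white adipocyte genes (adjusted p = 0.0143 each). Fry does not compare a list with other genes. Of the other 9 splits of the 6 libraries into 3 and 3, 5 gave as many camera calls or more.

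The de novo lipogenesis list was called lower in the cold by camera (adjusted p = 1.2e-07) but not with an estimated correlation (adjusted p = 0.511). Of its 16 tested members 12 fell and 0 rose, 13 and 0 when adjusted over the list alone, with a median log2 change of -2.88. Besides Fasn, Slc25a1, Scd1, Pnpla3, Me1 and Tkt, the falls included Thrsp, a regulator of lipogenesis (1818 ± 286 to 523 ± 194 CPM, -1.80 ± 0.27, adjusted p = 0.000558), Acss2, an acetyl-CoA synthetase (25.6 ± 15.5 to 1.77 ± 0.498 CPM, -3.74 ± 0.51), and Acaca, an acetyl-CoA carboxylase (13.9 ± 5.79 to 1.22 ± 0.835 CPM, -3.38 ± 0.52). Acly, the ATP citrate lyase that supplies cytosolic acetyl-CoA, fell from 27.2 ± 21.9 to 1.11 ± 1.40 CPM (-4.45 ± 0.84, adjusted p = 0.00437), a cold level near the 3-read floor of 1.01 to 1.03 CPM. Its change was -3.69 without control replicate 9 and -6.06 without cold replicate 4. Mlxipl, G6pdx, Elovl6 and Elovl5 did not pass, at -1.91 ± 0.74, -0.16 ± 0.34, -0.11 ± 0.31 and -0.10 ± 0.49. The status of Mlxipl (adjusted p = 0.0722) turns on the setting: it was called lower by DESeq2 (-2.05, adjusted p = 0.0261), with no count filter (-1.81, adjusted p = 0.00151), without control replicate 2 (-2.46, adjusted p = 0.0226) and without cold replicate 4 (-2.64, adjusted p = 0.0418).

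Genes of lipid uptake moved in both directions. Of 12 tested members of that list 5 rose and 3 fell, 5 and 4 when adjusted over the list alone (median 0.38, camera adjusted p = 0.408, fry adjusted p = 0.0237). Among the falls the call of Apoe was lost without control 14, cold 4 or cold 11. With Lpl rose Cd36, a fatty acid translocase (344 ± 61.2 to 708 ± 99.9 CPM, 1.04 ± 0.20, adjusted p = 0.00266), and Gpihbp1, which carries lipoprotein lipase to the capillary wall (494 ± 74.4 to 836 ± 70.1 CPM, 0.76 ± 0.18, adjusted p = 0.00801). The fatty acid binding proteins parted: Fabp3 rose from 384 ± 175 to 2927 ± 857 CPM (2.93 ± 0.34, adjusted p = 0.000221), Fabp5 fell from 5141 ± 977 to 1079 ± 297 CPM (-2.25 ± 0.23, adjusted p = 6.0e-05), and Fabp4 stood at 35074 ± 2612 and 37795 ± 2148 CPM (0.11 ± 0.12, adjusted p = 0.507). Slc27a2, an acyl-CoA synthetase, rose from 1.08 ± 0.514 CPM, under the control floor of 1.62 to 2.96 CPM, to 10.2 ± 1.67 CPM. Pltp, the phospholipid transfer protein, fell by 1.64 ± 0.35 (adjusted p = 0.00491), with exons that overlap Ctsa. Angptl4, an inhibitor of lipoprotein lipase, was not called (-0.02 ± 0.44, adjusted p = 0.985, 95% interval -0.99 to 0.96).

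Fatty acid oxidation, lipid droplet and triglyceride synthesis genes were called in part. In the oxidation list 7 of 22 tested members rose and 3 fell, 7 and 4 when adjusted over the list alone (median 0.28, camera adjusted p = 0.270). The rises were 4 without control 9 or cold 11, and the falls were 5 without control 2 and 1 without each cold library in turn. The rises included Etfdh, which passes electrons to the respiratory chain (141 ± 51.1 to 281 ± 11.1 CPM, 0.99 ± 0.25, adjusted p = 0.0121), and Cpt1b, the carnitine palmitoyltransferase of muscle and brown fat (0.97 ± 0.24), whose exons overlap Gm44502, while the thiolase Acaa2 fell by 0.90 ± 0.17. In the lipolysis and droplet list 4 of 13 rose and 0 fell, both over all genes and adjusted over the list alone (median 0.08, camera adjusted p = 0.408). The other 3 rises, of Plin5, Aqp7 and Mgll, depend on single libraries. Without cold 4 all 3 calls were lost, and without control 14 or cold 11 those of Aqp7 and Mgll. Without control 9 or cold 15 the call of Aqp7 was lost. Lipe was called lower without control 2, and Plin1 was called higher without cold 15. Cidec, a droplet protein, rose from 3986 ± 226 to 6266 ± 345 CPM (0.65 ± 0.13, adjusted p = 0.00313), while Cidea, its relative in brown fat, stood at 5376 ± 506 and 5689 ± 328 CPM (0.08 ± 0.13, adjusted p = 0.667, 95% interval -0.21 to 0.38). In the glycerol and triglyceride list 3 of 10 rose and 2 fell, again the same when adjusted over the list alone (median 0.18, camera adjusted p = 0.416). The falls, of Pck1 and Agpat2, were 0 without each cold library in turn and 1 without control 9 or 14, and the rise of Gpat4 was lost without control 9, cold 4 or cold 11. Dgat1, which makes triglyceride, rose from 1723 ± 305 to 3814 ± 192 CPM (1.15 ± 0.16, adjusted p = 0.000453), and Gk, the glycerol kinase, rose from 1.85 ± 0.684 CPM, near the control floor of 1.62 to 2.96 CPM, to 7.53 ± 1.41 CPM (adjusted p = 0.00580).

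Of 16 tested members of the thermogenesis list 5 rose and 2 fell, 6 and 2 when adjusted over the list alone (median 0.30, camera adjusted p = 0.310, fry adjusted p = 0.0345). Without cold 4 the counts were 3 and 1, with the calls of Aifm2, Letmd1 and S100b lost, and without cold 11 they were 4 and 0, with those of Letmd1, Cox8b and S100b lost. The falls were 1 without control 9 or cold 15. Elovl3, a fatty acid elongase of brown fat, rose from 6.32 ± 2.61 to 81.9 ± 27.7 CPM (3.69 ± 0.38, adjusted p = 6.1e-05), and the potassium channel gene Kcnk3 rose from 24.4 ± 1.90 to 62.1 ± 12.5 CPM (1.35 ± 0.24, adjusted p = 0.00176). For Ucp1 the 95% interval of the change ran from -0.42 to 0.16, so with TMM scaling a rise of more than 1.11-fold lay outside it. The interval does not include the choice of scaling or filter. The median change over all genes moved by 0.067 with totals alone, 0.12 with no count filter and -0.049 with DESeq2 size factors. Aifm2, an oxidoreductase of lipid droplets, rose from 9.11 ± 1.02 to 17.2 ± 1.67 CPM (0.93 ± 0.26, adjusted p = 0.0194). It was called on flow cell 2 alone (1.59, adjusted p = 0.00893) and not on flow cell 1 alone (0.44, adjusted p = 0.315), a difference that was not tested. Its call was also lost in DESeq2 (0.90, adjusted p = 0.132) and without control replicate 2 (0.89), control replicate 14 (0.85), cold replicate 4 (0.86) or cold replicate 15 (0.89). Dio2, which activates thyroid hormone, had 4 reads over all libraries, all in cold replicate 4. The coactivator gene Ppargc1a had 10, with 4 in cold replicate 11 and 6 in cold replicate 15. The leptin gene Lep had 1, in control replicate 9. These genes had too few reads to be tested, and the cold libraries were the deeper ones.

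Glycolytic genes moved in both directions, and both genes of the mitochondrial pyruvate carrier fell. Of 14 tested members of the glucose list 6 rose and 2 fell, 8 and 2 when adjusted over the list alone (median 0.58, camera adjusted p = 0.101). The rises were 4 without control 9, cold 4 or cold 11, with those of Slc2a4 and Pgk1 lost, and 9 without control 14. Pfkl, a phosphofructokinase, rose from 78.1 ± 31.5 to 320 ± 48.6 CPM (2.03 ± 0.30, adjusted p = 0.000588), and Gapdh (1.27 ± 0.19), Tpi1 (1.38 ± 0.22) and Ldhb (1.04 ± 0.21) rose too, while the enolase Eno1 (-1.10 ± 0.23, adjusted p = 0.00437) and the aldolase Aldoa (-1.01 ± 0.24, adjusted p = 0.00933) fell. In the pyruvate dehydrogenase and tricarboxylic acid list 7 of 24 fell and 0 rose, the same when adjusted over the list alone (median -0.18, camera adjusted p = 0.0752). The falls were 4 without control 14, cold 4 or cold 15, with the calls of Dlat, Idh2 and Sdhc lost, 5 without control 9 or cold 11, and 10 without control 2. Mpc1, a subunit of the mitochondrial pyruvate carrier, fell from 9076 ± 238 to 4427 ± 632 CPM (-1.04 ± 0.14, adjusted p = 0.000400), and the other subunit Mpc2 fell by 0.71 ± 0.14. The pyruvate dehydrogenase subunit genes Pdha1 (388 ± 63.2 to 188 ± 23.0 CPM) and Pdhb (1244 ± 125 to 621 ± 85.2 CPM) fell as well.

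Messenger RNAs encoded by the mitochondrial genome held a smaller share of reads in the cold, 5.20 ± 1.24% (SD, n = 3) in control and 2.59 ± 0.376% in cold libraries. These mRNAs lack the cap that the kit selects for. Their counts therefore also depend on how far uncapped RNA was carried through, which is weighed in the closing section. Of 12 tested mRNAs 11 fell and 0 rose, the same when adjusted over the list alone (median -1.27, camera adjusted p = 8.6e-06), with adjusted p = 0.511 with an estimated correlation. mt-Nd4, a complex I subunit, fell from 2750 ± 605 to 989 ± 13.5 CPM (-1.47 ± 0.18, adjusted p = 0.000191). mt-Atp6, an ATP synthase subunit, fell from 8906 ± 2910 to 2758 ± 255 CPM (-1.69 ± 0.21, adjusted p = 0.000215), and mt-Co2, a cytochrome oxidase subunit, fell by 1.54 ± 0.20. mt-Atp6 has a near-identical copy with reads in Gm10925 and mt-Co2 in Gm28661. mt-Co1 stood at 158 ± 67.5 and 237 ± 136 CPM (0.59 ± 0.44, adjusted p = 0.329).

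Nuclear genes of the respiratory chain and ATP synthase moved little. Of 73 tested members 13 fell and 2 rose, 11 and 2 when adjusted over the list alone, with a median of -0.24 (camera adjusted p = 0.00230) and adjusted p = 0.700 with an estimated correlation. The falls were 2 without cold 4 or cold 11, 7 without cold 15 and 11 to 14 without a control library, and the rises were 4 without control 2 and 1 without control 9, control 14, cold 11 or cold 15. Ndufa7 fell from 3307 ± 581 to 1744 ± 82.4 CPM (-0.92 ± 0.16, adjusted p = 0.00158) and Ndufs8 fell by 0.69 ± 0.17 (adjusted p = 0.00896), whereas Ndufa5 rose from 562 ± 40.8 to 1233 ± 132 CPM (1.13 ± 0.16, adjusted p = 0.000516); all are complex I genes. The call of Ndufs8 was lost without cold replicate 4 (-0.66, adjusted p = 0.0534) and with no count filter (-0.57, adjusted p = 0.0926). The list was not called once each library's trend of counts on transcript length was removed (median -0.11, adjusted p = 0.243) or without cold replicates 11 and 15 (median -0.19, adjusted p = 0.0796), alternatives chosen after seeing the data, nor by fry (adjusted p = 0.174).

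The list of endoplasmic reticulum folding and the unfolded protein response was called higher in the cold. Of its 8 tested members 5 rose and 0 fell, 6 and 0 when adjusted over the list alone, with a median of 1.11 (camera adjusted p = 0.00230) and adjusted p = 0.422 with an estimated correlation. Hspa5, the main chaperone of the reticulum, rose from 15.8 ± 5.27 to 171 ± 33.2 CPM (3.47 ± 0.30, adjusted p = 2.8e-05). Manf, a secreted stress-response factor, rose from 3.69 ± 1.37 to 22.8 ± 1.33 CPM (2.65 ± 0.33, adjusted p = 0.000213), and Herpud1, a part of protein degradation at the reticulum, rose from 15.98 ± 1.38 to 44.9 ± 0.832 CPM (1.48 ± 0.23, adjusted p = 0.000693). Calr, the chaperone calreticulin, and the transcription factor gene Atf4 rose by 1.34 ± 0.27 and 0.88 ± 0.18.

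Of 10 tested heat shock genes 5 rose and 0 fell, 6 and 0 when adjusted over the list alone, with a median of 1.12 (camera adjusted p = 0.0224) and adjusted p = 0.688 with an estimated correlation. The rises were 3 without control 2 and 2 without control 14. Bag3, a co-chaperone, rose from 5.42 ± 4.01 to 33.9 ± 10.8 CPM (2.69 ± 0.50, adjusted p = 0.00228). Its change was 2.10 without control replicate 2 and 3.44 without control replicate 14. Hspb1, a small heat shock protein, rose from 1051 ± 114 to 2214 ± 981 CPM (1.08 ± 0.26, adjusted p = 0.00964), a call lost without control replicate 2 (1.02), and Dnaja1 rose by 1.31 ± 0.34 (adjusted p = 0.0130), a call lost without control replicate 14 (1.14) or cold replicate 4 (1.19). Hsp90ab1 was not called without control replicate 14 (0.82, adjusted p = 0.0534), and Hspd1, called at adjusted p = 0.04998, lost its call without each library in turn (0.45 to 0.57). Hspb6 (16.1 ± 8.64 to 262 ± 346 CPM, adjusted p = 0.116) and Cryab (4.14 ± 2.19, adjusted p = 0.229), chaperones abundant in muscle, moved with the skeletal muscle markers described below. Hspb6 was called higher by DESeq2 (3.99, adjusted p = 0.00732), without cold replicate 4 (4.53, adjusted p = 0.0272) and without cold replicate 15 (1.96, adjusted p = 0.0292). The list was not called without cold replicate 15 (median 0.71, adjusted p = 0.0776), without cold replicates 11 and 15 (median 0.73, adjusted p = 0.0796) or by fry (adjusted p = 0.0618).

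Of 77 tested cytosolic ribosomal protein genes 9 fell and 2 rose, 7 and 2 when adjusted over the list alone, with a median of -0.26 (camera adjusted p = 0.0216) and adjusted p = 0.765 with an estimated correlation. The falls were 3 without cold 4 or cold 11, 22 without cold 15 and 7 to 11 without a control library, and the rises were 5 without control 2 and 1 without control 9, control 14, cold 4 or cold 15. Rps24 fell by 1.19 ± 0.22 (adjusted p = 0.00191) and Rpl18 fell by 1.34 ± 0.30 (adjusted p = 0.00580), while Rpl35 rose from 82.1 ± 28.2 to 269 ± 52.8 CPM (1.70 ± 0.28, adjusted p = 0.000993). Near-identical copies with reads exist for 11 members of the list. The list was not called without control replicate 2 (median -0.04, adjusted p = 0.430), cold replicate 4 (median -0.26, adjusted p = 0.0632) or cold replicate 11 (median -0.14, adjusted p = 0.333), by fry (adjusted p = 0.474) or once the trend on transcript length was removed (median -0.14, adjusted p = 0.378). Of 24 tested proteasome genes 5 rose and 1 fell, 3 and 1 when adjusted over the list alone (median 0.13, camera adjusted p = 0.472, fry adjusted p = 0.0237), with Psma2 at 1.13 ± 0.26 and Psma1 at 0.95 ± 0.22 among the rises. The rises were 3 without control 9 or each cold library in turn, with that of Psmb5 lost in each case, and the falls were 2 without cold 15.

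**Figure D3:**
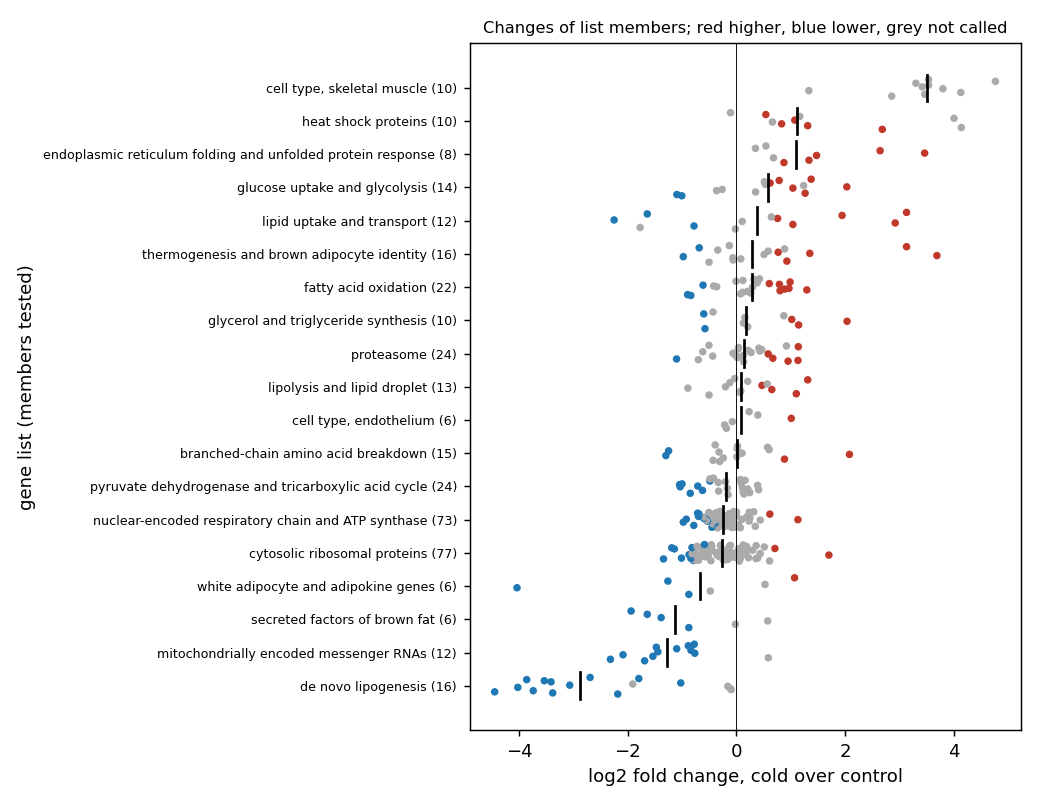
Each tested member of the 19 tested gene lists is a point at its log2 change, cold minus control, with the list median marked. The de novo lipogenesis list lies lowest with a median of -2.88, the mitochondrially encoded mRNAs have a median of -1.27, and the skeletal muscle markers, none of them called, have a median of 3.50.

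In the branched-chain amino acid list 2 of 15 rose and 2 fell, the same when adjusted over the list alone. Dbt, the core of the branched-chain dehydrogenase, rose by 2.08 ± 0.39 and the transaminase Bcat2 by 0.89 ± 0.22, while the dehydrogenase kinase Bckdk fell by 1.30 ± 0.25. The median of this list was 0.01 and the camera direction was down (adjusted p = 0.694), and with DESeq2 size factors the median was -0.04. Of 6 tested secreted factors of brown fat 4 fell and 0 rose, 4 and 1 when adjusted over the list alone (median -1.13, camera adjusted p = 0.0873, fry adjusted p = 0.0143). They were Pltp, Adipoq, the adiponectin gene (1914 ± 248 to 1043 ± 103 CPM, -0.88 ± 0.16, adjusted p = 0.00220), Rbp4, the retinol binding protein (-1.94 ± 0.40), and Nrg4 (-1.39 ± 0.33), whose call was lost in DESeq2 (-1.42, adjusted p = 0.0568). Of 6 white adipocyte genes 3 fell, namely Car3, Adipoq and the haptoglobin gene Hp (-1.26 ± 0.22), and 1 rose, Retn, which encodes resistin (1.07 ± 0.27), a call lost without cold replicate 4 (0.81), while Cfd was called higher without control 14 or cold 11. The counts were 3 and 2 when adjusted over the list alone (median -0.68, camera adjusted p = 0.117, fry adjusted p = 0.0143).

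Lists with fewer than 5 tested members were not tested as sets, and their counts were the same when adjusted over the list alone. Dbp, a clock output gene, fell from 88.3 ± 32.3 to 18.6 ± 8.57 CPM (-2.23 ± 0.36, adjusted p = 0.000995), and Nr1d1, the other tested clock gene, was not called (0.41 ± 0.38, adjusted p = 0.440). Of 3 creatine and calcium cycling genes, Ckb rose and so did Alpl, an alkaline phosphatase, from 0.561 ± 0.542 CPM, under the control floor, to 10.4 ± 2.52 CPM (adjusted p = 0.000588). The third, the mitochondrial creatine kinase Ckmt2, was not called by edgeR (4.47 ± 1.82, adjusted p = 0.140) and moved with the skeletal muscle markers, while it was called higher by DESeq2 (4.43, adjusted p = 0.00917) and without cold replicate 4 (5.02, adjusted p = 0.0264). In the cyclic AMP and immediate early list the 1 tested gene, Klf9, rose (0.95 ± 0.29, adjusted p = 0.0271), and in the cell cycle list the 1 tested gene, the histone gene H2afz, rose (0.67 ± 0.21, adjusted p = 0.0277). Of 2 cholesterol synthesis genes Nsdhl fell (-1.72 ± 0.50, adjusted p = 0.0219) and Fdps was not called (-0.56 ± 0.28). Of 3 matrix genes the crosslinking enzyme Loxl1 rose (1.03 ± 0.33, adjusted p = 0.0329), Mgp fell (-1.07 ± 0.37, adjusted p = 0.0444) and Sparc was not called (-0.28 ± 0.16), except with the trend on transcript length removed (-0.45, adjusted p = 0.0190). The calls of Klf9, H2afz, Nsdhl, Loxl1 and Mgp were each lost on leaving out 1 library: Klf9 without control 2, control 9, cold 11 or cold 15 (0.80 to 0.93), H2afz without control 9, control 14 or any cold library (0.60 to 0.72), Nsdhl without control 9 (-1.48) or cold 4 (-1.80), Loxl1 without control 2, control 9, cold 4 or cold 11 (0.84 to 1.00) and Mgp without those same libraries (-0.78 to -1.06).

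Markers of skeletal muscle, which borders this depot, differed between the cold libraries. The 10 tested markers together held 200, 696 and 1142 CPM in control replicates 2, 9 and 14, and 260, 3365 and 15984 CPM in cold replicates 4, 11 and 15. None of the 10 was called by edgeR (median 3.50, camera adjusted p = 0.102), with 0 at an unadjusted p under 0.05, and none was called when adjusted over the list alone. Limma-voom called 0, and DESeq2 called Mb (4.11, adjusted p = 0.0122) of the 9 it gave an adjusted p. Without cold replicate 4, edgeR called Mb, Tnnt3 and Myl1 higher. Their ratio between cold replicates 15 and 4 ran from 15.7 to 290, with a median of 64.9. Des and Tpm2 of the smooth muscle list moved with them (2.98 ± 1.31 and 3.39 ± 1.60, adjusted p = 0.162 and 0.188), and none of the 4 tested genes of that list was called by edgeR. DESeq2 called both higher (adjusted p = 0.0409 for Des and 0.0463 for Tpm2), and Des was also called without cold replicate 4 (3.49, adjusted p = 0.0153).

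Markers of the other cell types gave 1 call. Eng, the endothelial receptor endoglin, rose from 66.0 ± 15.6 to 133 ± 4.27 CPM (1.01 ± 0.23, adjusted p = 0.00633), the only 1 of 6 tested endothelial genes over all genes and adjusted over the list alone (median 0.08, camera adjusted p = 0.694). The median of that list was -0.25 without control replicate 2. The fibroblast genes Dpt (0.64 ± 0.41, called higher without control replicate 9 at 1.19, adjusted p = 0.0343) and Dcn (0.41 ± 0.40), the macrophage gene C1qa (0.23 ± 0.33) and the 4 tested globin genes (median -0.27) were not called, over all genes or adjusted over the list alone. Without control 14 edgeR called the globin genes Hba-a1 and Hba-a2 lower. No lymphocyte or Schwann cell gene had reads enough to be tested with all 6 libraries. Leaving out 1 library let further genes past the count filter. Of these, the Schwann cell gene Mbp was called lower without control 14, and the macrophage gene Cd74 was called lower without control 9 or 14.

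**Figure D4:**
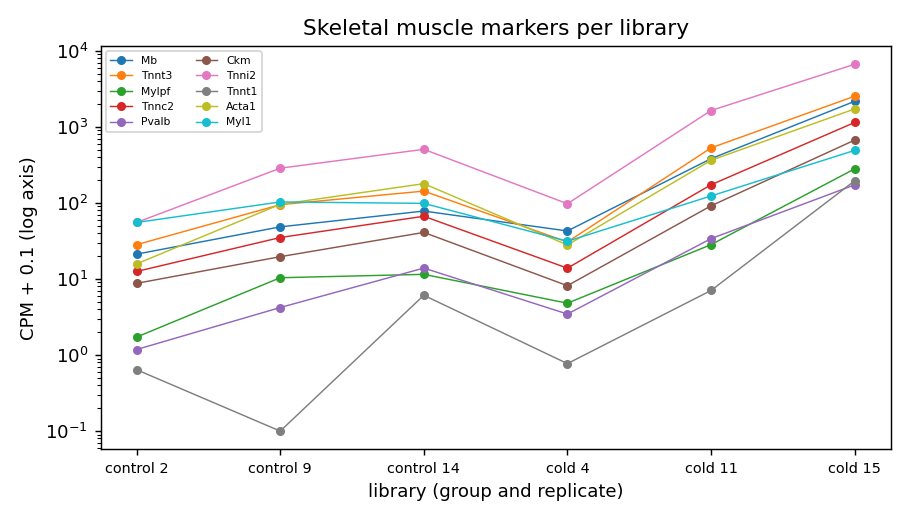
The level of each of the 10 tested skeletal muscle markers is shown per library as CPM plus 0.1 on a log axis. All 10 are highest in cold replicate 15, and their sum runs from 200 CPM in control replicate 2 to 15984 CPM in cold replicate 15.

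Reads were assigned to transcripts, so the comparison was repeated for each transcript. Gnas-221 and Gnas-211, transcripts of the stimulatory G protein gene, rose from 18.7 ± 1.20 to 64.2 ± 8.70 CPM (1.78 ± 0.24, adjusted p = 0.000211) and from 85.3 ± 7.29 to 211 ± 11.1 CPM (1.30 ± 0.20, adjusted p = 0.000431), although Gnas as a gene was not called. Polr1d-201, of an RNA polymerase subunit gene, rose from 16.5 ± 3.54 to 45.0 ± 1.60 CPM (1.42 ± 0.26, adjusted p = 0.00131), and Dbi-202, of the acyl-CoA binding protein gene, fell from 180 ± 46.0 to 41.5 ± 5.36 CPM (-2.11 ± 0.24, adjusted p = 7.8e-05). Cavin1-201 (-0.91 ± 0.31, adjusted p = 0.0425) and Dap3-201 (-0.87 ± 0.31, adjusted p = 0.0493) were called but overlapped between groups. Each of these calls was lost on leaving out any library other than control replicate 2, with changes of -0.64 to -0.99 for Cavin1-201 and -0.51 to -0.99 for Dap3-201. Of 2787 transcripts tested by edgeR, 912 were called, 485 higher and 427 lower. Of these, 849 followed their gene's call, 2 opposed it and 61 belonged to genes that were not called. Without cold replicates 11 and 15 together 411 were called, 388 of them among the 912.

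The share of a gene's reads held by each transcript shifted in few genes. In 1700037H04Rik the transcript 207, annotated as a target of nonsense-mediated decay, fell from 33.3 ± 4.00% to 5.41 ± 1.41% of reads (SD, n = 3), and the retained-intron transcript 204 held 63.2 ± 4.89% in control and 94.1 ± 1.45% in cold (edgeR gene adjusted p = 8.3e-08). In Dbi, transcript 202 fell from 6.50 ± 2.02% to 1.39 ± 0.0908% of reads while transcript 204 held 49.7 ± 1.16% and 53.4 ± 0.539% (edgeR gene adjusted p = 6.5e-06). Rps24-210 rose from 6.36 ± 1.58% to 20.8 ± 2.60% and Rps24-205 held 54.8 ± 3.25% and 41.5 ± 3.58% (edgeR gene adjusted p = 0.00466). Adtrp-201 fell from 26.8 ± 10.7% to 5.66 ± 0.728% of its gene's reads, with Adtrp-202 at 67.1 ± 9.34% and 91.0 ± 0.564% (edgeR gene adjusted p = 0.00466). Of 539 genes tested by diffSpliceDGE, 8 were called and 26 had an unadjusted p under 0.05.

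The other 4 called genes had higher adjusted p values. The transcripts behind the calls of Adtrp, BC004004, Aes and Ramp2 had few reads over all libraries, with 159 for Adtrp-201, 82 for BC004004-215, 191 for Aes-207 and 209 for Ramp2-203. Gnas-211 held 2.47 ± 0.226% of its gene's reads in control and 5.41 ± 0.501% in cold, and Gnas-202 63.9 ± 2.51% and 59.7 ± 1.56% (edgeR gene adjusted p = 0.0161). BC004004-215 held 25.5 ± 11.2% and 6.01 ± 1.85%, and BC004004-201 68.8 ± 10.1% and 77.5 ± 4.61% (edgeR gene adjusted p = 0.0221). The retained-intron transcript Aes-207 held 4.62 ± 1.30% and 17.1 ± 3.55%, and Aes-201 93.6 ± 2.95% and 81.1 ± 3.14% (edgeR gene adjusted p = 0.0286). Ramp2-203, whose exons overlap Vps25, held 9.01 ± 3.51% and 26.5 ± 7.30%, and Ramp2-204 67.9 ± 2.20% and 53.7 ± 3.17% (edgeR gene adjusted p = 0.0286). In Aifm2, transcripts 201 and 203 held 26.3 ± 9.72% and 40.1 ± 2.68% in control and 41.7 ± 4.32% and 33.2 ± 5.24% in cold, with no call (edgeR gene adjusted p = 1.00), and no Ppargc1a transcript had reads enough to be tested. Leaving out 1 library called 5 genes without control replicate 2, cold replicate 4 or cold replicate 11, 2 without control replicate 9 or 14 and 7 without cold replicate 15. In each of these runs 1700037H04Rik and Dbi were called, and they were the only ones without control replicate 9 or 14 and without cold replicates 11 and 15 together. Dbi and Gnas were not called among transcripts with at least 5% of their gene's counts, a setting that removes Dbi-202. Adtrp was not called on flow cell 2 alone or at equal depth, and Ramp2 not on flow cell 2 alone. BC004004 was not called on either flow cell alone, at equal depth or with at least 20 counts in at least 3 samples. Aes was not called on flow cell 1 alone, at equal depth, under that count filter or with diffSplice of limma. Some of these genes had too few reads to be tested there. 1700037H04Rik and Rps24 were called under each of these settings.

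**Figure D5:**
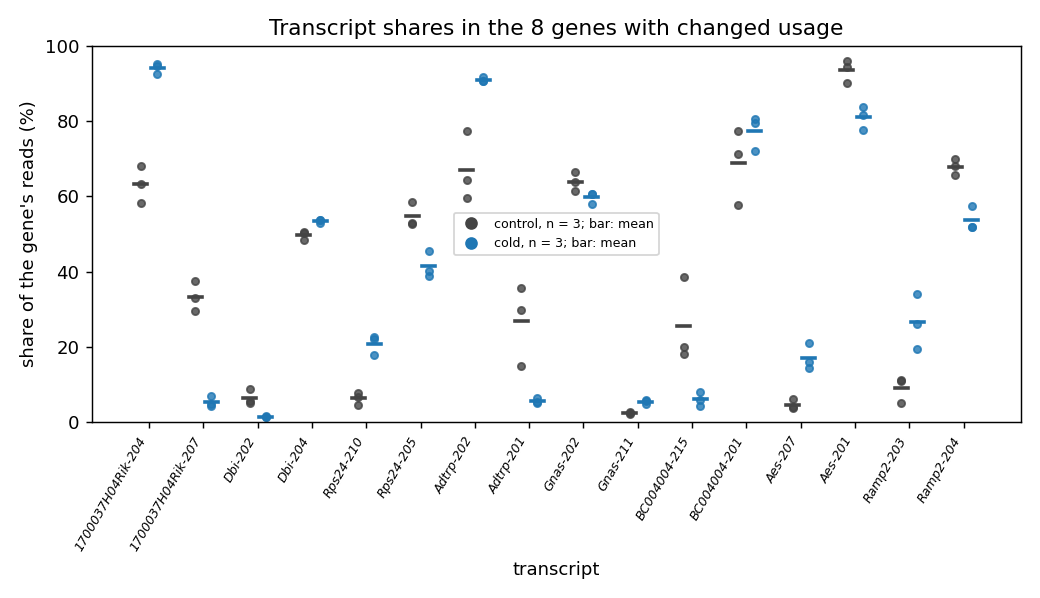
The share of its gene's reads held by each named transcript is shown per library as a percent, with group means. In 1700037H04Rik the 3 cold libraries hold 92.4 to 95.2% of reads on transcript 204, above the 3 control libraries at 58.2 to 68.0%.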

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

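Removal of the trend on transcript length and leaving out cold replicates 11 and 15 together were alternatives chosen after seeing the data, and all others were chosen before. Under the latter 498 to 708 genes and 611 to 914 transcripts were called, and 755 genes with the length trend removed. With cold replicates 11 and 15 left out together the counts were 321 genes, 411 transcripts, 2 genes with changed usage and 4 lists, in a design with only 1 cold library, whose spread is taken from the controls. At equal depth 532 genes were called, and 512 of the 589 earlier calls still tested were called in the same direction. The balance of calls depends on scaling: 54.4% of called genes were higher with TMM, 50.0% with DESeq2 size factors and 60.6% with totals alone. With no count filter 63.4% were higher, in a fit whose median over all genes moved by 0.12. Leaving out 1 library gave 2 to 7 genes with changed usage and 5 to 8 lists, and camera with an estimated correlation called 0 lists. The cause of these differences between settings was not tested.

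The named and example genes kept their direction and their side of the threshold in 2110 comparisons with an alternative. They lost the call in 155, gained one in 14 and changed direction in 18. The changes of direction were all in genes not called under either setting. Angptl4 was at 0.050 with totals alone, 0.10 with limma-voom, 0.12 with no count filter and 0.058 on flow cell 2 alone. With no count filter Elovl5 was at 0.012 and Elovl6 at 0.020. Leaving out 1 library gave -0.37 to 0.66 for Angptl4, -0.025 to 0.13 for Cidea, -0.49 to 0.065 for G6pdx, -0.66 to 0.35 for Elovl5 and -0.39 to 0.11 for Elovl6. It gave -0.022 to 0.84 for mt-Co1, -0.14 to 4.70 for Cryab, whose lowest value is that without cold replicate 15, and -0.23 to 0.45 for C1qa. The cause was not tested. Flow cell 1 alone put Acly at -5.43 and Acss2 at -4.42, and flow cell 2 alone put them at -3.78 and -3.12. At equal depth Acly was at -5.16 and Mmd at -2.47, and on flow cell 2 alone Cntfr was at 4.80.

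In simulated data of this size 31 of 100 changes of 2-fold were recovered, with 93 of the 100 past the count filter. The simulation changed 200 genes, fewer than the 695 called in the data. The Benjamini-Hochberg adjustment was therefore stricter there, and the recovered share cannot be carried over to the data as it stands. The parts of depth, replicate number and spread between libraries in this recovery were not separated. A gene that was not called is not shown to be unchanged.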

Other observations

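The genes of these opening paragraphs lie outside the fixed lists and were chosen after their values were seen. Slc2a5, a fructose transporter, fell from 53.4 ± 32.1 CPM (SD, n = 3) to 0.998 ± 0.340 CPM, at the 3-read floor of the cold libraries of 1.01 to 1.03 CPM (edgeR adjusted p = 6.0e-05). Slc25a17, a peroxisomal carrier, rose from 147 ± 18.2 to 699 ± 133 CPM (2.25 ± 0.21), Acot8, a thioesterase, rose from 14.1 ± 1.24 to 71.0 ± 2.84 CPM (2.34 ± 0.23), and Abcd3, a membrane transporter, rose from 76.3 ± 29.3 to 264 ± 47.9 CPM (1.80 ± 0.30). No list of peroxisomal genes was fixed, and of the 8 tested genes of the Pex family, of peroxisome assembly, 2 rose (camera adjusted p = 0.536, fry adjusted p = 0.0488).

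Txnrd1, a thioredoxin reductase, rose from 15.6 ± 6.52 to 53.6 ± 3.91 CPM (1.83 ± 0.30, edgeR adjusted p = 0.000995) and the peroxiredoxin Prdx6 from 101 ± 14.5 to 322 ± 24.3 CPM (1.67 ± 0.20, edgeR adjusted p = 0.000191). The glutathione transferases Gstm1, Gstm2 and Gstm5 fell by 1.37 ± 0.23, 2.01 ± 0.30 and 2.56 ± 0.33. The calcium binding protein genes S100a10 and S100a11 fell from 979 ± 218 to 216 ± 11.2 CPM and from 803 ± 113 to 203 ± 14.2 CPM (edgeR adjusted p = 3.9e-05 for each). Timm50, of mitochondrial protein import, rose by 1.92 ± 0.23, and Sco2, of cytochrome oxidase assembly, by 1.89 ± 0.31, with exons that overlap Ncaph2.

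The runs without each library were chosen before the counts were read, and the tests of the splits of the libraries were written before their results were seen. The tests on muscle markers, nuclear copies, the length trend, ribosomal RNAs, untested genes and symbol families, and the use of the runs without each library to weigh a fall, were chosen after the result was seen. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The labelled split gave 695 genes, 912 transcripts and 8 genes with changed usage, where the highest of the other splits gave 0 in each case, so 1 of 10 splits reached each count. Each of the other splits mixes cold and control libraries in both groups. A difference between cold and control then adds to the spread within groups, so the 0 calls cannot show how many calls chance gives. For gene lists 6 of the 10 splits gave as many calls as the 6 of the labelled split, and the highest of the others gave 9.

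The first pattern weighed is the spread of skeletal muscle markers: all 10 tested markers were highest in cold replicate 15, and their ratios to cold replicate 4 had a median of 64.9. Such a shared rise goes with skeletal muscle carried along with the fat in cold replicates 11 and 15 and equally with a response, and the same markers had shown the pattern. All cold libraries lay above all controls in 0 of the 10 markers. This cannot decide on a rise in every cold mouse, since the mice are not paired. The summed markers of the controls ran from 200 to 1142 CPM, around the 260 CPM of cold replicate 4. A response in some or all mice and muscle in the dissection cannot be told apart, since no other part of the tissue was measured. The most abundant markers in cold replicate 15 were Tnni2 at 6638, Tnnt3 at 2523 and Mb at 2163 CPM, none of the 10 is held by another list, and all 10 also had reads in cold replicate 4.

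The second pattern is the fall of mitochondrially encoded mRNAs: with the reads of 7 near-identical nuclear copies added the median change was -1.35, which argues against reads moved to nuclear copies. With each library's trend on transcript length removed it was -1.16, and 8 of the 12 mRNAs were still called lower, which argues against that trend as the whole cause. The 2 uncapped mitochondrial ribosomal RNAs held 0.0816% of control and 0.135% of cold reads, a log2 ratio of 0.73 with groups that overlap (mean log2 difference 0.77, 95% interval -0.44 to 1.99), and their share over that of the mRNAs was higher in each cold than in each control library (mean log2 difference 1.77, 95% interval 0.39 to 3.14). This argues against a lower carry-through of uncapped RNA in the cold libraries as the whole cause, as far as both kinds of RNA are carried through alike, which was not tested. A lower level of mitochondrial transcripts in the cold stays open, as a hypothesis not tested by another assay.

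The third pattern is the small fall of respiratory chain and ribosomal protein genes: across genes, which are not independent replicates, change and annotated length correlated (Spearman rho 0.187), and the median change was -0.19 among the 419 shortest genes and 0.27 among the 419 longest. With the trend removed the ribosomal median was -0.14, from -0.26, with an SD over members of 0.499 against 0.495, and the respiratory median was -0.11, from -0.24, with an SD of 0.343 against 0.341. Both calls ended (adjusted p = 0.378 and 0.243), with the median over all genes moved by -0.087, so the trend may account for part of the fall and cannot be told apart from a response to cold. Removal of 3 libraries, each alone, ended the ribosomal call (control replicate 2 at a median of -0.04, cold replicate 4 at -0.26 and cold replicate 11 at -0.14), and removal of no other library alone did so. The respiratory call ended for no library alone, but it did so without cold replicates 11 and 15 together (median -0.19, adjusted p = 0.0796).

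Many list genes had too few reads to test. The 271 untested genes had a median annotated length of 2360 nucleotides and the 389 tested ones 996. Within lists the untested genes were longer by 0.34 on the log2 scale beyond shuffles (permutation p = 1e-05, the smallest that 100000 resamples can give). This suggests that long mRNAs are missed by the assay, although the expression level of the untested genes was not known and lower expression could give the same. Of 42 families of genes with a shared symbol stem 0 passed camera after adjustment, 6 had an unadjusted p under 0.05, and fry called 12, so whether such families move together in the cold was not settled. Several of the families hold genes of the fixed lists, among them Cox, Rpl and Rps, which are 3 of those 6.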
